A study of Mus musculus with 9 samples.

How the data were processed

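Total RNA depleted of ribosomal RNA from β-TC6 cells was sequenced from strand-specific libraries. The 9 samples were grouped by their labels into control, palmitic acid and stearic acid, with 3 in each group. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with Trimmomatic 0.30, aligned to mm10 with HISAT2 2.0.1, counted with HTSeq 0.6.1 and compared with DESeq, for which no version is given. The assembler of the transcripts, the tool behind the expected counts, the strand setting of counting and the annotation are not given in the sources used here.

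The deposited lncRNA table gives an expected count (an estimated read count per transcript, 77.7% of them whole numbers) and an FPKM for each library, with coordinates, strand, class and exon numbers per transcript. The deposited FPKM values were not tested, since counts exist, and were used only to check the unit. The authors' comparison tables give log2 fold changes with their standard errors, p-values and adjusted p-values, in columns of the kind DESeq2 writes. The deposited table of calls across comparisons holds 1 or 0 per transcript and comparison. Every transcript in the authors' comparison tables had an adjusted p under 0.05 and an absolute log2 fold change above 1, with the largest adjusted p at 0.0483, 0.0500 and 0.0472 and the smallest absolute log2 change at 1.01, 1.00 and 1.02 for palmitic acid, stearic acid and stearic against palmitic acid. A deposited heatmap file was not used, since it holds colour codes alone.

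The count table lists 15589 lncRNA transcripts at 9635 loci, of which 11806 have a count above 0 in a library. It classes 10285 as intergenic, 4306 as antisense and 998 as intronic, and 4293 as known. Coordinates were compared with GENCODE mouse release 21 (GRCm38): of 10600 transcripts with an Ensembl identifier, 10462 identifiers are in that release, and 99.96% of these overlap the gene there, 82.7% on the same strand. Coding genes within 10 kb and genes overlapping on the opposite strand were taken from the same release. Only the lncRNA counts are in the table, so library totals are totals over lncRNAs.

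Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Transcripts were filtered with filterByExpr, which left 4426, libraries were scaled with TMM, and a quasi-likelihood model was fitted to all 9 samples, with 6 residual degrees of freedom and a biological coefficient of variation of 0.564. The 3 comparisons were palmitic acid against control, stearic acid against control and stearic against palmitic acid. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. Tests were two-sided. CPM values use the TMM-scaled library size, and intervals are 95% confidence intervals from the fit. For a group at 0, a fold is a lower bound against 3 counts over the group. Tested on simulated data with 200 changed transcripts, the fit called 2%, 6% and 4% of 2-fold changes and 24%, 36% and 29% of 4-fold changes in the 3 comparisons in that order. Of 4-fold changes with a base mean over 100 counts it called 73.3%, 85.7% and 94.4%, and 2, 2 and 0 unchanged transcripts were called.

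Lists with at least 5 tested transcripts were tested with camera in limma 3.58.1, at the preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Of 21 lists, 15 had tested members. They were snoRNA host, imprinted, abundant nuclear, stress and p53, immune and islet lncRNAs, lncRNAs within 10 kb of genes of endoplasmic reticulum stress, inflammation, fatty acid oxidation and PPAR, sterol synthesis and desaturation, apoptosis and p53, and the cell cycle, and of marker genes of β, α, δ, PP, acinar and duct cells, macrophages, fibroblasts and endothelial cells. Categories with at least 5 calls were tested with Fisher's exact test. Shared controls were simulated 20 times with no changes between groups.

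The naming rule, the comparisons and the lists were fixed before the data were examined. Named transcripts are those in the series title and, among the calls of a comparison, the 8 most increased and 8 most decreased of those at or above the median expression of the calls, the 5 of highest expression, up to 10 per list, and the 5 of smallest adjusted p called with both acids. This gave 11 names for palmitic acid, 24 for stearic acid and 1 for the comparison of the acids. Alternatives fixed in advance were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, fits of only the 2 groups compared, the replicate number as a block, each replicate left out, and stricter thresholds. Alternatives chosen after seeing the data were counts summed per locus (3039 loci tested, biological coefficient of variation 0.204), DESeq2 with a prior on fold changes, scaling by library size alone, and a fit without the most abundant transcript. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.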

Results

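Long non-coding RNAs (lncRNAs) were measured in β-TC6 cells, a mouse line grown from an insulin-secreting tumour of pancreatic β cells, to find those that respond to saturated fatty acids. The 9 libraries form 3 groups of 3, an untreated control, palmitic acid and stearic acid. Each acid was given at 400 µmol/L for 24 h with 1.3% bovine serum albumin, and whether the control cells received albumin is not given in the sources used here. If the control cells received none, a change against control could come from albumin as well as from the acid. Palmitic and stearic acid are saturated fatty acids of the diet whose chains differ by a pair of carbon atoms. The labels do not say that replicates were separate cultures, so they may be technical. Counts assigned to lncRNA transcripts summed to 1839123, 2103773 and 2870275 in the control libraries, to 2755266, 2737777 and 2484333 with palmitic acid, and to 1948925, 1537431 and 2418397 with stearic acid. Between 6850 and 7554 lncRNA transcripts had a count above 0 in a library. A floor of 3 counts equalled 1.05 to 1.95 CPM (counts scaled to a common library size), depending on the library, and covers counting error only. The transcript with the most counts, TCONS_00215072, lies over the immunoglobulin pseudogene Igkv13-57-2 and took 22.3% ± 3.50 of control counts, 20.1% ± 1.42 with palmitic acid and 21.8% ± 6.31 with stearic acid (SD, n = 3). Stearic acid replicate 2 stood apart, with the lowest total, the highest share of TCONS_00215072 (28.7%) and a second principal component score of 50.6, where the other libraries lay between −31.6 and 8.91.

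Palmitic acid was compared with control to find lncRNAs that respond to the most common saturated fatty acid of blood plasma. A lncRNA antisense to Mafa, the gene of a transcription factor that drives insulin expression, fell from 2455 ± 136 to 971 ± 29.3 CPM (TCONS_00088788, mean ± SD, n = 3), 2.53-fold lower. Igf2os, antisense to the imprinted growth factor gene Igf2 and next to the insulin gene Ins2, fell from 2312 ± 279 to 837 ± 74.1 CPM (TCONS_00233737, n = 3), 2.76-fold lower. Gm12962, a lncRNA with no described function in the annotation used, fell from 302 ± 43.4 to 102 ± 20.2 CPM (TCONS_00184470, n = 3), 2.97-fold lower. TCONS_00038546, within 10 kb of the RNA helicase gene Dhx40, rose from 134 ± 17.3 to 308 ± 18.3 CPM (n = 3), 2.30-fold. Gm10552, antisense to the immune chromatin gene Sp140, rose from 99.8 ± 11.3 to 215.3 ± 7.39 CPM (TCONS_00009134, n = 3), 2.16-fold. For each of these 5 lncRNAs, all 3 palmitic acid libraries lay beyond all 3 control libraries.

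The palmitic acid changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for 18 of 4426 tested transcripts, 13 higher and 5 lower, at 18 loci. The Mafa antisense lncRNA (chromosome 15, 75745489 to 75746963 of mm10, 2 exons) had a log2 change of −1.34 ± 0.11 (SE) and an edgeR adjusted p of 0.00346. TCONS_00038546 (chromosome 11, 86811658 to 86816394) had a log2 change of 1.20 ± 0.12 and an edgeR adjusted p of 0.0126. Igf2os (chromosome 7, 142659693 to 142670356, −1.47 ± 0.19), Gm12962 (chromosome 4, 131638991 to 131656265, −1.57 ± 0.20) and Gm10552 (chromosome 1, 85609853 to 85611896, 1.11 ± 0.13) each had an edgeR adjusted p of 0.0207. The other named increases were the Csmd3 antisense transcript TCONS_00088303 (log2 change 1.80), 9230114K14Rik near Dhx15 (1.49), TCONS_00068951 on chromosome 13 (1.37), TCONS_00111079 on chromosome 17 (0.95) and TCONS_00146205 on chromosome 2 (0.77), with edgeR adjusted p from 0.0207 to 0.0483. The 5 decreases also included 4933401H06Rik (TCONS_00167285, log2 change −2.68) and TCONS_00184465 (−2.84), which are outside the naming rule and were chosen after their values were seen. At an unadjusted p under 0.05, 497 transcripts differed, where chance would give 221.3. Without any single library, 5 transcripts passed (without control replicate 2) or 1 (without control replicate 1, control replicate 3 or any palmitic acid replicate), and the Mafa antisense lncRNA passed in all 6 of these fits. Scaled by library size alone, an alternative chosen after the data were seen, 13 transcripts passed, 8 of them higher.

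**Figure D1:**
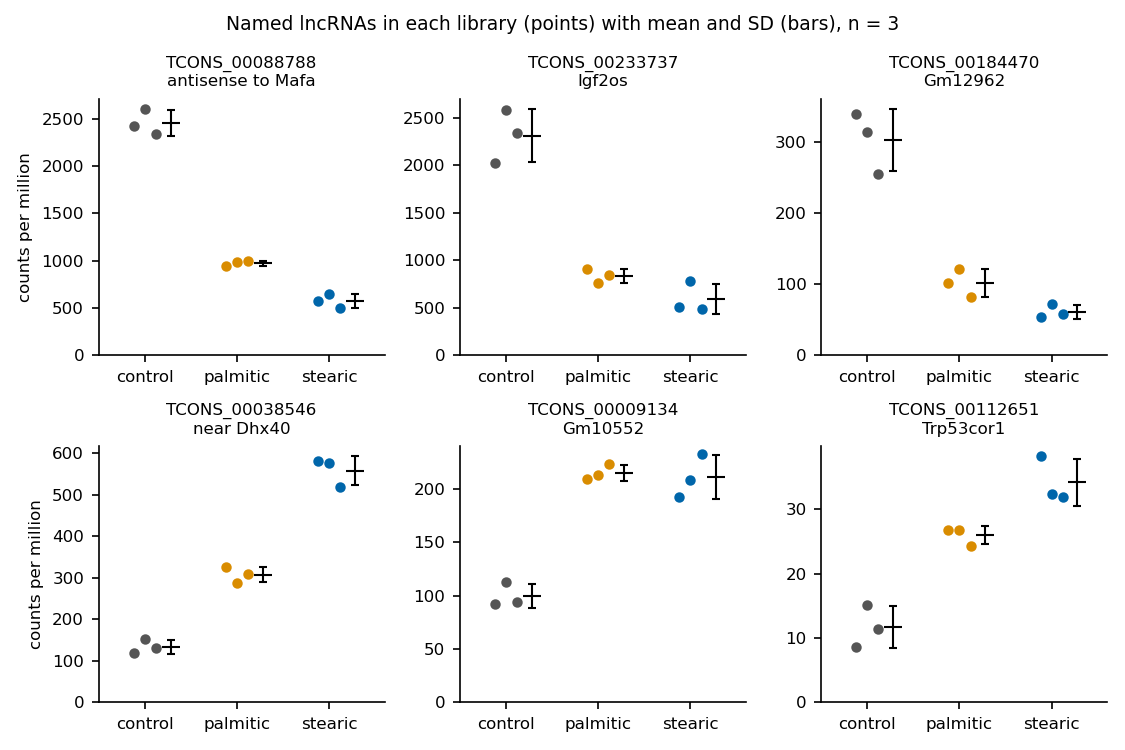
CPM (vertical axes, counts scaled to TMM library sizes) of 6 lncRNAs in control, palmitic acid and stearic acid libraries, with 1 point per library and bars for the mean and SD (n = 3 per group). The Mafa antisense lncRNA falls from 2455 to 971 and 570.0 CPM, TCONS_00038546 near Dhx40 climbs from 134 to 308 and 558 CPM, and Trp53cor1 from 11.7 to 34.2 CPM with stearic acid.

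Lists of lncRNAs and of genes with lncRNAs inside 10 kb of them were fixed before the data were examined. Transcripts at β-cell genes (45 at 17 loci, including those antisense to Mafa and next to Ins2) moved down with palmitic acid: 0 rose, 2 fell (the Mafa antisense lncRNA and Igf2os) and 43 did not pass. Adjusted over the list alone, 3 fell and 0 rose. The list's median log2 change was −0.19 and its mean −0.25, with a camera adjusted p of 0.000411, or 0.0227 with the correlation estimated from the data. Summed per locus, the β-cell list had a camera adjusted p of 0.000113, or 0.0592 with the estimated correlation, so that call was then lost. The imprinted lncRNAs (16, of which 5 are Igf2os) included 1 decrease, or 2 adjusted over the list alone. Their median log2 change of 0.01 differed in sign from the mean of −0.36 and from the test, which gave down with a camera adjusted p of 0.00679, or 0.0437 with estimated correlation. Stress and p53 lncRNAs (25, of which 15 are transcripts of Pvt1, the lncRNA next to Myc) included 0 changes over all transcripts and 2 increases adjusted over the list alone. Their median log2 change was 0.48, with a camera adjusted p of 0.00199, or 0.0437 with estimated correlation. Islet lncRNAs (31, of which 15 are the same Pvt1 transcripts, so the 2 lists are not separate evidence) included 0 changes in either count, a median log2 change of 0.33 and a camera adjusted p of 0.00409, or 0.0437 with estimated correlation. The calls of the imprinted, stress and islet lists with palmitic acid were lost per locus, with a camera adjusted p of 0.229, 0.0600 and 0.0821, or 0.307, 0.191 and 0.275 with estimated correlation. The lists share members: all 31 islet lncRNAs, 20 of the stress lncRNAs, 12 of the nuclear, 9 of the β-cell and 8 of the imprinted transcripts are in another list.

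None of the other lists tested passed with palmitic acid. Abundant nuclear lncRNAs such as Malat1 and Neat1 (18 transcripts) had 0 changes, a median log2 change of 0.29 and a camera adjusted p of 0.0830. Transcripts near endoplasmic reticulum stress genes (10, camera adjusted p = 0.807), sterol and desaturase genes (9, camera adjusted p = 0.389) and apoptosis and p53 genes (6, camera adjusted p = 0.897) also had 0 changes. For the apoptosis list the median log2 change of −0.05 differed in sign from the mean of 0.41. Lists with under 5 tested members had no set test and 0 changes over all transcripts with either acid: snoRNA hosts (3), immune lncRNAs (1), inflammatory genes (2), cell cycle (2), α cell (3), δ cell (1) and macrophage genes (1). Adjusted over the list alone, Lncenc1, the tested member of the immune list, was higher with each acid, and 1 transcript each at inflammatory and δ-cell genes was lower with stearic acid. In the fit of loci, Lncenc1 rose from 1.56 ± 1.35 to 7.32 ± 1.59 and 10.7 ± 2.86 CPM (edgeR adjusted p = 0.0454 and 0.00597). The α-cell list locus Gm20554 also passed there with stearic acid (log2 change 0.48, edgeR adjusted p = 0.0480). Lists for fatty acid oxidation and PPAR targets, PP, acinar, duct, fibroblast and endothelial cells had 0 tested members.

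**Figure D2:**
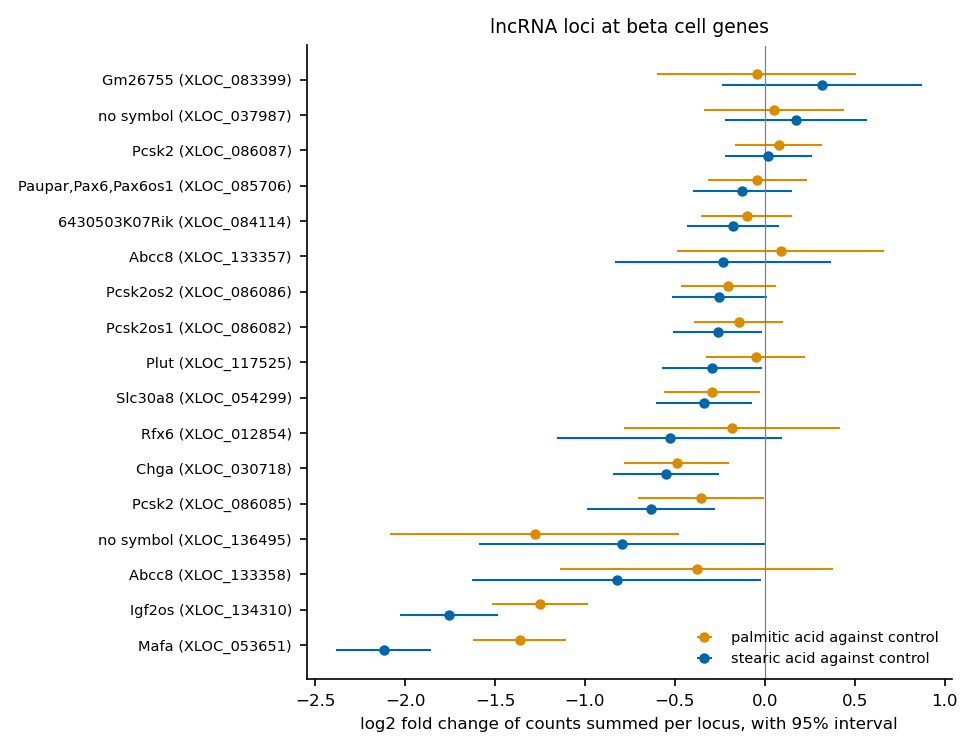
Log2 change against control (horizontal axis) of the summed counts of 17 lncRNA loci at β-cell genes (vertical axis), palmitic acid in orange and stearic acid in blue, with 95% confidence intervals as bars (n = 3 libraries per group). The Igf2os locus (−1.25 and −1.76) and the Chga antisense locus (−0.49 and −0.55) lie below 0 with both acids, and loci such as Slc30a8 (−0.30 and −0.34) did not pass the test.

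Stearic acid was compared with control to find lncRNAs that respond to the longer saturated acid, which the series title links to β-cell inflammation. The Mafa antisense lncRNA fell to 570.0 ± 74.0 CPM (TCONS_00088788, n = 3), 4.31-fold lower than control, and Igf2os, which lies next to the insulin gene, fell to 590.5 ± 162 CPM (TCONS_00233737), 3.92-fold lower. TCONS_00038546 near Dhx40 rose to 558 ± 35.4 CPM, 4.17-fold higher. Trp53cor1 (lincRNA-p21), a p53 target, rose from 11.7 ± 3.27 to 34.2 ± 3.60 CPM (TCONS_00112651, n = 3), 2.91-fold higher. E230016M11Rik, within 10 kb of the p53 target Gadd45a, fell from 34.0 ± 4.85 to 12.3 ± 2.93 CPM (TCONS_00214972, n = 3), 2.76-fold lower. Pvt1, a stress lncRNA next to Myc, rose in transcript TCONS_00088508 from 29.9 ± 2.36 to 76.8 ± 6.56 CPM (n = 3) and fell in transcript TCONS_00088523 from 25.5 ± 21.9 CPM to 0 in all 3 libraries. For each of these transcripts, all 3 stearic acid libraries lay beyond all 3 control libraries. The fall of TCONS_00088523 was at least 51.0-fold against a floor of 3 counts over the stearic acid group, or at least 25.6-fold without control replicate 1, which had the highest value of the control libraries. The counts of all 21 Pvt1 transcripts together rose from 212 ± 15.5 to 417 ± 32.5 CPM (log2 change 0.97 ± 0.13, edgeR adjusted p = 2.12e-05 over loci). With palmitic acid this sum also rose, to 334 ± 13.2 CPM (0.66 ± 0.13, edgeR adjusted p = 0.00326 over loci). Trp53cor1 also passed with palmitic acid in the fit of loci (1.12 ± 0.26, edgeR adjusted p = 0.0102), though not in that of transcripts (edgeR adjusted p = 0.104).

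The stearic acid changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for 63 of 4426 transcripts, 36 higher and 27 lower, at 54 loci. TCONS_00120303 and TCONS_00120304, 2 of the 63 chosen here after their values were seen, have the same counts in every library and are a single measurement. The Mafa antisense lncRNA had a log2 change of −2.11 ± 0.11 (SE) and an edgeR adjusted p of 8.92e-05, TCONS_00038546 of 2.06 ± 0.13 and 0.000166, and Gm12962 of −2.31 ± 0.20 and 0.00219. Igf2os transcripts TCONS_00233737 and TCONS_00233734 changed by −1.97 ± 0.19 and −1.62 ± 0.17, with edgeR adjusted p of 0.00361 and 0.00442. Trp53cor1 (chromosome 17, 29057474 to 29078961) changed by 1.54 ± 0.25, with an edgeR adjusted p of 0.0295, and E230016M11Rik by −1.46 ± 0.25, with an edgeR adjusted p of 0.0357. Of the other named transcripts, Gm27168 (log2 change −2.36), TCONS_00185019 (−1.63), Dtnbos (−1.16) and TCONS_00079147 (−1.11) fell. Those antisense to Csmd3 (1.61 to 1.77), near Gstp3 (1.69), Dhx15 (1.64) and Tex36 (1.57), on chromosome 13 (1.59), antisense to Sp140 (1.08), opposite the recombination gene Rad51b (0.46) and near the repair gene Ercc4 (0.47) rose. At an unadjusted p under 0.05, 676 transcripts differed, where chance would give 221.3. Without any single library, 8 (control replicate 3), 13 (stearic acid replicate 3), 20 (control replicate 2), 23 (control replicate 1), 31 (stearic acid replicate 2) or 33 (stearic acid replicate 1) transcripts passed. The Mafa antisense lncRNA, both Igf2os transcripts, Gm12962, TCONS_00038546 and TCONS_00068951 passed in all 6 fits. Trp53cor1 and E230016M11Rik passed in 1, and both Pvt1 transcripts, Dtnbos, TCONS_00056759 (Rad51b), TCONS_00079147 and TCONS_00128285 (Gstp3) in 0. For lncRNAs antisense to Mafa, Igf2, Csmd3, Sp140, Dtnb, Rad51b, Chga and Pcsk2, the sources used here do not say whether counting used the strand, and without it reads of a gene and of its antisense partner cannot be told apart.

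The β-cell list moved down with stearic acid as well: 0 transcripts rose, 3 fell (the Mafa antisense lncRNA and 2 Igf2os transcripts) and 42 did not pass. Adjusted over the list alone, 7 fell and 1 rose. The list's median log2 change was −0.26, with a camera adjusted p of 5.11e-06, or 0.00789 with estimated correlation, and the call held per locus (camera adjusted p = 3.71e-06, or 0.0286). At single loci, the lncRNA antisense to Chga, the gene of a protein of insulin granules, fell from 342 ± 28.2 to 235 ± 35.2 CPM (log2 change −0.55, edgeR adjusted p = 0.0123). Of 4 lncRNA loci named Pcsk2, after the insulin-processing gene they lie at, or Pcsk2os, XLOC_086085 fell from 146 ± 26.3 to 94.7 ± 18.8 CPM (log2 change −0.63, edgeR adjusted p = 0.0172). The most abundant of them, XLOC_086087, was at 3159 ± 28.1 and 3198 ± 294 CPM (0.02, edgeR adjusted p = 0.954), and Pcsk2os1 (−0.26, edgeR adjusted p = 0.169) and Pcsk2os2 (−0.25, edgeR adjusted p = 0.219) did not pass either. Stress and p53 lncRNAs included 2 increases (Trp53cor1 and Pvt1) and 1 decrease (Pvt1), or 6 and 1 adjusted over the list alone. Their median log2 change was 0.52, with a camera adjusted p of 0.00186, or 0.0346 with estimated correlation. Islet lncRNAs included 1 increase and 1 decrease, both of Pvt1, or 8 and 1 adjusted over the list alone, with a median log2 change of 0.41 and a camera adjusted p of 0.00208, or 0.0346 with estimated correlation. With Pvt1 TCONS_00088523 at its bound, the mean log2 changes of the stress and islet lists were 0.36 and 0.37. Abundant nuclear lncRNAs included 0 changes, or 1 increase adjusted over the list alone, with a median log2 change of 0.44 and a camera adjusted p of 0.00270, or 0.0346 with estimated correlation. Miat, one of the nuclear and islet lncRNAs, rose as a locus from 15.4 ± 6.03 to 47.4 ± 7.48 CPM (n = 3, log2 change 1.61, edgeR adjusted p = 0.000199), while Malat1 did not pass (0.35, edgeR adjusted p = 0.0780). The imprinted lncRNAs included 2 decreases, both Igf2os, or 4 adjusted over the list alone. Their median log2 change of 0.01 differed in sign from the mean of −0.46 and from the test (camera adjusted p = 0.00650, or 0.0346 with estimated correlation). Per locus with estimated correlation, the calls of these 4 lists with stearic acid were lost. The camera adjusted p per locus was 0.00454 for the stress list (0.0734 with estimated correlation), 0.00454 for the islet list (0.0812), 0.06465 for the nuclear list (0.184) and 0.252 for the imprinted list (0.297). Lists near endoplasmic reticulum stress genes (median log2 change 0.36, camera adjusted p = 0.0741), sterol and desaturase genes (0.802) and apoptosis and p53 genes (0.479, with E230016M11Rik as the 1 decrease) did not pass. For the sterol list the median of 0.08 differed in sign from the mean of −0.08, and for the apoptosis list the median of 0.03 from the test.

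TCONS_00077866, the lncRNA that the series title names, was examined by itself. It lies on the plus strand of chromosome 14 (72982042 to 72986780, 3 exons) in an intergenic locus of 7 transcripts. It had 0 counts in every control library, 11.45 counts in 1 palmitic acid library and 0 in the others, and 30.6, 34.55 and 37.4 counts in the stearic acid libraries. Its mean with stearic acid was 17.9 ± 4.997 CPM (SD, n = 3), at least 40.8-fold higher than control against a floor of 3 counts over the control group, and with palmitic acid 1.36 ± 2.36 CPM, at least 3.11-fold higher, all of it from palmitic acid replicate 1. In edgeR's quasi-likelihood test the adjusted p was 0.114 for stearic acid against control, 0.478 for palmitic acid against control and 0.956 for stearic against palmitic acid, so no difference passed. Leaving out a library gave edgeR adjusted p of 0.208 to 0.247 for stearic acid against control. For stearic acid against control, it passed with the DESeq2 Wald test, with no filter on low counts, in a fit of only the 2 groups compared and with DESeq2 with a prior on fold changes. Stearic against palmitic acid did not pass in any of these. In the deposited comparison tables its log2 change was 4.05 ± 0.57 (authors' DESeq adjusted p = 5.95e-10) against control and 1.59 ± 0.41 (authors' DESeq adjusted p = 0.0284) against palmitic acid. Whether those log2 changes were shrunken toward 0 is not given in the sources used here, and a fit here with a prior that does so (DESeq2, 2 groups) gave 3.62 against control, so they are not comparable with the bound of at least 40.8-fold. All 7 transcripts together rose from 32.9 ± 3.31 CPM to 56.8 ± 7.36 with palmitic acid (log2 change 0.78 ± 0.19, edgeR adjusted p = 0.0125 over loci) and to 66.9 ± 10.4 with stearic acid (1.03 ± 0.19, edgeR adjusted p = 0.000674). The palmitic acid call of the locus was lost without control replicate 2 (log2 change 0.71) or palmitic acid replicate 3 (0.68). Between the acids the locus differed by 0.25 (95% interval −0.13 to 0.62, edgeR adjusted p = 0.814). Saa3 and miR-297b-5p, also in the title, were not analysed here, and no lncRNA with counts lay within 10 kb of Saa3.

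**Figure D3:**
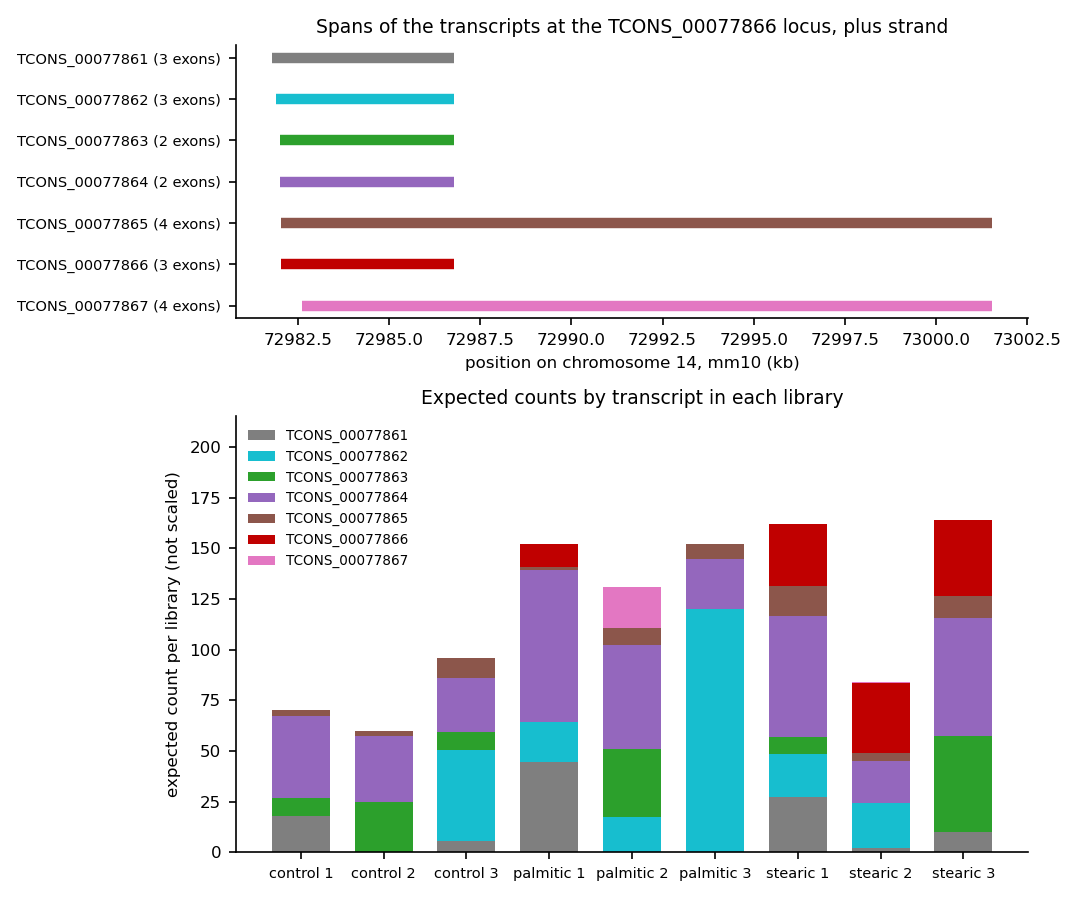
Spans of the 7 transcripts of the TCONS_00077866 locus on the plus strand of chromosome 14 (horizontal axis in kb, top) and their stacked unscaled expected counts in each of the 9 libraries (bottom), with a colour per transcript. TCONS_00077866 adds 30.6 to 37.4 counts in the stearic acid libraries, 11.45 in 1 palmitic acid library and 0 in the control libraries, and other transcripts of the locus are counted in all groups.

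Stearic acid was compared with palmitic acid, its shorter analog, at the same dose and time. The Mafa antisense lncRNA was 1.70-fold lower with stearic than with palmitic acid (log2 difference −0.77, 95% interval −1.02 to −0.52, n = 3) and TCONS_00038546 near Dhx40 was 1.81-fold higher (0.86, 0.58 to 1.138), each with an edgeR adjusted p of 0.161, so neither passed. Gm10552 at the immune gene Sp140 differed by −0.03 (95% interval −0.32 to 0.27). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 4426 transcripts, and 216 had an unadjusted p under 0.05, where chance would give 221.3. The DESeq2 Wald test called 10, DESeq2 with a prior on fold changes 4, and edgeR with no filter on low counts 17. Of the 66 transcripts called with either acid, the 95% interval of the difference excluded 0 for 21 and contained 0 for 45, with a median half-width of 0.55 on the log2 scale. These intervals are not adjusted. The 66 were selected on values that also form the difference, which by itself can push it away from 0. The 21 are therefore no evidence of a difference between the acids. In simulated data of this size, 29% of 4-fold and 4% of 2-fold changes were called between the acids. None of the lists passed in the fit of transcripts. The β-cell, endoplasmic reticulum stress and nuclear lists had a camera adjusted p of 0.0607 (unadjusted camera p of 0.0227, 0.0195 and 0.0227), and the others of 0.320 (apoptosis), 0.454 (islet, sterol) and 0.515 (imprinted, stress). For the imprinted list (median 0.05, mean −0.10), the stress list (0.14, −0.31) and the islet list (0.12, −0.16) the median differed in sign from the mean, and in the imprinted list from the test. With Pvt1 TCONS_00088523 at its bound the means of the stress and islet lists were −0.19 and −0.05. Adjusted over the list alone, 1 transcript each of the imprinted, stress, islet, apoptosis and β-cell lists was lower with stearic acid. Per locus, the islet (0.0447), endoplasmic reticulum stress (0.0342) and β-cell (0.0378) lists had a camera adjusted p under the threshold, each 0.140 with estimated correlation.

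With counts summed per locus, an alternative chosen after the data were seen, 3 of 3039 loci passed between the acids. The Mafa antisense and Dhx40 loci hold 1 transcript each, so summing left their counts unchanged and only the fit differed. Its median total degrees of freedom (residual ones plus those gained by sharing the spread across loci) were 23.4, against 8.83 in the transcript fit. The Mafa antisense locus was lower with stearic acid (log2 difference −0.76 ± 0.12 SE, 95% interval −1.01 to −0.50, edgeR adjusted p = 0.00494). The locus near Dhx40 was higher, at 557 ± 36.8 against 304 ± 19.3 CPM (0.87 ± 0.14, edgeR adjusted p = 0.00394). A locus near the glutathione transferase gene Gstp3 (chromosome 19, 4061040 to 4069495) was higher, at 944 ± 55.0 against 575 ± 64.3 CPM (0.72 ± 0.13, edgeR adjusted p = 0.00920, n = 3). The number of loci was 0 without palmitic acid replicate 2, 1 without stearic acid replicate 3, 2 without palmitic acid replicate 1 or stearic acid replicate 1, and 4 without stearic acid replicate 2.

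The changes with the 2 acids were set side by side to see which lncRNAs moved with both. Transcripts changed by both acids numbered 15, of which 12 rose, including TCONS_00038546 near Dhx40, Gm10552 at Sp140 and 9230114K14Rik near Dhx15, and 3 fell, the Mafa antisense lncRNA, Igf2os and Gm12962. Independent lists would share 0.106 increases and 0.0305 decreases, and simulated groups without changes that shared 3 controls had 0 shared calls on average over 20 simulations. The 3 control libraries serve both comparisons and cannot be split. Part of the excess over independent lists can therefore come from shared controls, and the simulations share controls but hold no changes. Albumin came with both acids, and whether the control cells received it is not given in the sources used here. If they did not, an effect of albumin would appear in both comparisons. From these libraries it cannot be told apart from an effect shared by the acids, and the simulations do not cover it. Another 3 transcripts were called with palmitic acid alone (TCONS_00111079, 4933401H06Rik and TCONS_00184465) and 48 with stearic acid alone, and all 66 had the same sign with both acids. The 66 were selected against the same controls, which by itself favours equal signs, and the simulations give no value for selected transcripts. Across all 4426 transcripts, which are not independent replicates, the log2 changes with the 2 acids correlated at 0.611, against 0.491 (highest 0.555) in the simulations. Their covariance was 0.890 against 0.366 (highest 0.456), a difference of 0.525 from the simulated mean, and 74.1% had the same sign against 66.2% (highest 67.5%). The simulations draw each transcript independently. Spread that many transcripts of a control library have in common is not in them, so they may understate what shared controls add. Without a library the number shared was 1 (without control replicate 1, control replicate 3 or any palmitic acid replicate), 5 (without control replicate 2), 9 (without stearic acid replicate 3) or 14 (without stearic acid replicate 1 or 2). Where the library was of an acid, only the calls of that acid were refitted. The calls of the other acid came from the main fit, which kept that library, so these overlaps can look steadier than reduced fits of both acids.

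**Figure D4:**
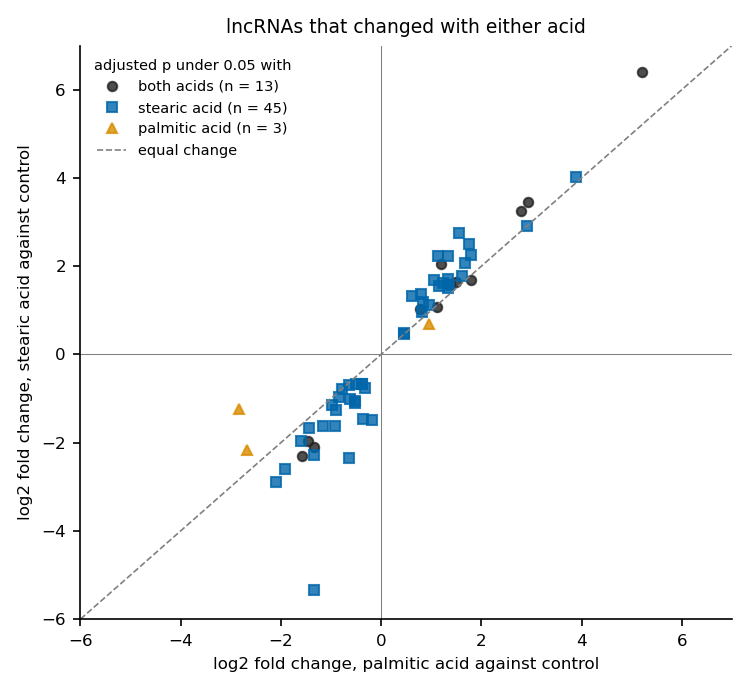
Log2 change with stearic acid (vertical axis) against log2 change with palmitic acid (horizontal axis), both against control, for 61 lncRNA transcripts called with either acid and with an expected count above 0 in every group (some far from 0 rest on few counts in a group), with circles for both acids, squares for stearic acid alone and triangles for palmitic acid alone, and a dashed line for equal change. All 61 have the same sign with both acids, for example the Mafa antisense lncRNA (−1.34 and −2.11) and TCONS_00038546 (1.20 and 2.06). Their selection against shared controls by itself favours equal signs. Among them, 2610020C07Rik (8.62 and 8.80) lies beyond the axes and is not drawn.

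The calls were tested for class, chromosome and neighbouring genes to see whether a kind of lncRNA was over-represented. Of 13 Fisher's exact tests, each of a category among the increases or decreases with an acid, none passed with Benjamini-Hochberg adjustment. The decreases with palmitic acid had no category with enough calls to test. Chromosome 1 held 6 of the 36 transcripts that rose with stearic acid (16.7%, against 6.71% of those tested), with the smallest p of 0.0306 by Fisher's exact test and an adjusted p of 0.398.

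The authors' deposited calls were compared with the test used here. Their tables list 81 transcripts with palmitic acid (53 higher, 28 lower), 189 with stearic acid (101 higher, 88 lower) and 17 between the acids (7 higher, 10 lower with stearic acid). Both acids share 32 increases and 19 decreases, and 0 transcripts in opposite directions. Of these calls 80, 167 and 16 were tested here, all with the same sign, and 15, 51 and 0 passed edgeR's test, while 77, 159 and 15 had an unadjusted p under 0.05. Calls with 0 counts in all libraries of a group numbered 8, 37 and 7.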

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

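The tests per locus, with DESeq2 with a prior on fold changes, with library size alone and without the most abundant transcript were chosen only after the result was seen, as was the use of the other alternatives on the overlap and the lists. In the order palmitic acid, stearic acid and stearic against palmitic acid, the counts of 18, 63 and 0 changed transcripts became 81, 163 and 10 with the DESeq2 Wald test, 48, 115 and 17 with no filter on low counts, and 169, 358 and 3 with counts summed per locus. They became 7, 28 and 0 in fits of only the 2 groups compared, which use fewer samples. DESeq2 with a prior, also on 2 groups, gave 82, 86 and 4. Library size alone gave 13, 34 and 0 (8 and 22 of them higher), DESeq2 size factors 13, 61 and 0, and a fit without the most abundant transcript 23, 58 and 0. The cause of these shifts was not tested, apart from the locus sums. The 15 calls shared by both acids became 60 (DESeq2 Wald test), 34 (no filter), 6 (only 2 groups), 33 (prior), 136 (per locus), 1 (adjusted p under 0.01) and 6 (absolute log2 change of at least 2).

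With a library left out the counts ranged from 1 to 5, 8 to 33 and 0 to 2, and the overlap from 1 to 14. Palmitic acid gave 5 calls without control replicate 2 and 1 without control replicate 1, control replicate 3 or each palmitic acid replicate. Stearic acid gave 8 without control replicate 3, 13 without stearic acid replicate 3, 20 without control replicate 2, 23 without control replicate 1, 31 without stearic acid replicate 2 and 33 without stearic acid replicate 1. The comparison of the acids gave 2 without stearic acid replicate 2 and 0 without each of the others. The overlap was 9 without stearic acid replicate 3, 5 without control replicate 2, 1 without control replicate 1, control replicate 3 or each palmitic acid replicate, and 14 otherwise. These fits have fewer samples. For the overlap without a library of an acid, the calls of the other acid came from the main fit, which kept that library. Per locus the ranges were 104 to 115, 236 to 332 and 0 to 4. The call of the TCONS_00077866 locus with palmitic acid was lost without control replicate 2 (log2 change 0.71) or palmitic acid replicate 3 (0.68). Without palmitic acid replicate 1 both groups are at 0 for TCONS_00077866, so that setting gave no palmitic acid value.

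The replicate number as a block gave 1, 16 and 0 transcripts and an overlap of 1. The numbers do not pair the samples: the 9 same-number pairs correlated at −0.0211 to 0.0681, none over 0.1, and 1 of 9 libraries correlated best with its own number in both other groups. The block therefore spends degrees of freedom on no shared signal. The list calls numbered 9 or 10 in the other fits of transcripts, against 9. Per locus they numbered 7, of which 4 are among the 9 (β cell with each acid, stress and islet with stearic acid) and 3 are calls between the acids, and 1 (β cell with stearic acid) with estimated correlation. No class or chromosome category passed under any background tried. Of the named transcripts, 0 reversed direction. All 11 palmitic acid results kept their side of the threshold with the DESeq2 Wald test, as did 23 of 24 for stearic acid, with TCONS_00077866 now past it. The threshold was no longer passed, for palmitic and stearic acid in that order, by 5 of 10 and 11 of 24 in fits of only the 2 groups, 0 and 4 with the prior, 0 and 3 with no filter, 2 and 0 with DESeq2 size factors, and 9 and 12 with the replicate block. In fits that left out a library, 13 palmitic acid results kept their side of the threshold and 52 no longer passed, and 66 and 78 for stearic acid. The results that kept their side include those of TCONS_00077866, which passed neither in the main fit nor in any of these. Pseudocounts, a filter on mean values and rescaling of normalized values were not run, since counts exist, nor were permutation tests of single transcripts. Depth sets a floor of 1.05 to 1.95 CPM per library. Of simulated 2-fold changes 2% to 6% were called, and how much of that is due to depth was not tested.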

Other observations

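The tests of other splits of the transcript counts, of the other transcripts at the TCONS_00077866 locus, of β-cell list members that overlap no listed gene and of the size of the stearic acid change were chosen only after the result was seen. So was the naming of the loci in the last paragraph.

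For each comparison the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Palmitic acid gave 18 transcripts, with 1 at most in the other splits, and 1 of the 10 splits gave as many. Stearic acid gave 63, with 1 at most in the others, and 1 split gave as many. Stearic against palmitic acid gave 0, with 1 at most in the others, and 10 splits gave as many. Per locus the 3 comparisons gave 169, 358 and 3, with 1, 1 and 0 at most in the others, and in each 1 split gave as many.

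Counts summed per locus passed the test more often than single transcripts, for which a candidate explanation is that reads are divided unevenly among the transcripts of a locus from library to library. At similar expression, transcripts at loci with several tested transcripts had 2.20 times the dispersion of transcripts that are alone at their locus (95% resampling interval 1.87 to 2.41, 2302 against 1548 transcripts), which goes with it. It is not the whole gain, since loci with a single transcript also passed more often in that fit (58 against 5 with palmitic acid and 131 against 15 with stearic acid). Summing leaves the counts of these loci as they were, so their extra calls came with the fit. Its median total degrees of freedom were 23.4, against 8.83 for transcripts, and its biological coefficient of variation 0.204, against 0.564. Which part of the fit gave these calls was not tested. Calls by the authors or here with 0 counts in every library of a group, at loci with several transcripts, numbered 47. Of these, 12 had a locus sum also called in that direction (25.5%, exact 95% interval 13.9% to 40.3%). The interval treats calls as independent, but some transcripts enter in several comparisons that share libraries, such as TCONS_00119905 with each acid. Another 7 calls are between the acids, where 0 of the 7 had a called locus sum and only 3 loci passed in all. A share of 25.5% goes with reads that moved between transcripts of a locus, for some of the calls without a called locus sum. For TCONS_00077866 such a move alone would lower the other transcripts of its locus with stearic acid. Together they changed by 0.59 (95% interval 0.14 to 1.04, log2, edgeR adjusted p = 0.0815). The interval holds no fall, which argues against it as the whole cause, though the rise did not pass. They rose by 0.74 with palmitic acid (edgeR adjusted p = 0.0400) and differed by −0.15 between the acids (95% interval −0.58 to 0.28). A move of reads beside a rise of the whole locus therefore stays open.

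LncRNAs at β-cell genes moved down with both acids, though per locus with estimated correlation the palmitic acid call was lost (camera adjusted p = 0.0592). Scaling or the most abundant transcript was examined as a source of that direction. With DESeq2 size factors or without that transcript, the highest median log2 change of the list was −0.20, but these settings moved the median of all transcripts by at most 0.0140, too little to have reversed the list, so the bound set for that test was wrong and it decides nothing. Scaling shifts all transcripts of a comparison alike, and camera compares the list with the others. The list's median was −0.19 with palmitic acid and −0.26 with stearic acid, where that of all transcripts was −0.00200 and 0.00982. These values argue against scaling as the reason that the list lay below the other transcripts. Reads of a coding gene counted on the lncRNA that overlaps it stay open, and from these tables the gene and its lncRNA cannot be told apart. The 8 list members that overlap no listed gene still moved down (camera p of 6.74e-06 with palmitic acid and 3.40e-06 with stearic acid), but 4 of them are Igf2os transcripts that overlap the coding gene Igf2, which the list does not hold. That test's bound was therefore wrong too, and the 4 others are too few to decide. A lower activity of β-cell genes, the biological reading of the groups, was not tested, since coding genes were not analysed here.

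Of the 18 transcripts called with palmitic acid, 12 had a larger absolute change with stearic acid (exact binomial sign test, two-sided p = 0.238), so a larger change with stearic acid was not established for them. Their median absolute log2 change was 2.08 with stearic acid and 1.69 with palmitic acid. Per locus it was 103 of 169 (exact binomial sign test, two-sided p = 0.00546), but loci share the same libraries and are not independent. Both sets were selected by their palmitic acid calls, which by itself favours larger palmitic acid changes. An even share is therefore not the right reference for either sign test. These counts restate the difference between the acids and test no explanation for it.

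Several loci changed with both acids as sums without a transcript named above. Gm13807, within 10 kb of the tetraspanin gene Cd82, rose from 4.22 ± 1.44 to 28.7 ± 5.94 CPM with palmitic acid and 40.1 ± 9.82 with stearic acid (SD, n = 3, edgeR adjusted p = 6.20e-06 and 1.85e-07). A neighbouring locus at Cd82 (chromosome 2, 93472982 to 93475093) rose from 0.285 ± 0.253 to 11.7 ± 3.24 and 17.1 ± 2.06 CPM. The locus antisense to Map3k8, a kinase gene of inflammatory signalling, rose from 4.78 ± 2.78 to 23.3 ± 7.32 and 25.5 ± 4.68 CPM (edgeR adjusted p = 0.000298 and 0.000134). Gm11588 rose from 18.9 ± 3.01 to 75.9 ± 6.62 and 95.4 ± 13.4 CPM (edgeR adjusted p = 4.45e-07 and 7.58e-09). The locus antisense to Cdh8 fell from 749 ± 43.9 to 423 ± 35.8 and 349 ± 35.5 CPM. Whether counting used the strand is not given in the sources used here, so the Map3k8 and Cdh8 values are not separable from reads of those coding genes.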
